A study of Mus musculus with 6 samples.

How the data were processed

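Uteri of mice on gestation day 5 were profiled by RNA sequencing, with 3 SRC-2f/f control mice and 3 SRC-2d/d mutant mice, each library coming from a different mouse according to the study's design text. SRC-2 is a coactivator of steroid receptors and is encoded by Ncoa2. Libraries were made from total RNA with a stranded, poly(A)-selecting mRNA kit, per the labels' protocols. HISAT2, HTSeq and DESeq are named per the submitters' processing notes, with no version. The genome build, the gene annotation, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. No genomic coordinates are therefore printed, and genes are identified by the symbols of the deposited table.

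The deposited table holds 1 value per gene and library, with 37060 genes. It is titled as FPKM by the authors, but its values were not FPKM. In each library all values (100%) were whole multiples of the smallest value above 0, within a tolerance of 1e-06 of a read, whatever the length of the gene. The inverse of that smallest value equalled the median-of-ratios size factor, which was 1.14, 0.935 and 0.982 in controls 1 to 3 and 0.880, 0.961 and 1.21 in mutants 1 to 3. The deposited values are thus a signal made of gene read counts divided by a size factor per library, and they are called normalized counts below. They are not corrected for gene length, so levels of different genes are not comparable. Dividing by the step gave back the whole reads assigned to genes. They came to 153621821, 138811835 and 163196592 reads in controls 1 to 3 and to 129905950, 149141641 and 195782326 reads in mutants 1 to 3. At this depth 3 reads, the limit set by a count of 0, correspond to a normalized count of 2.48 to 3.41 per library. Intervals given for genes with 1 to 3 reads are 95% exact Poisson intervals and cover counting error only.

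The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, on the assumption of FPKM values. The planned test was kept as written and applied to the normalized counts. It was limma (version 3.58.1, R 4.3.3), with lmFit and eBayes with trend on log2(normalized count + 1), for the 36154 genes with a mean of at least 0.5 over the 6 libraries. Mutants were compared with controls in a fit with genotype as the only term, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Unless another tool is named, an adjusted p is from this fit. Fold changes on this scale understate the change of genes with low counts. Levels are given as mean ± SD over 3 mice, and log2 differences as mutant minus control with their standard error (SE). Ncoa2 was also tested with an exact two-sided permutation test.

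Fixed lists of genes were tested with camera (two-sided, preset inter-gene correlation of 0.01), again with an estimated correlation, and with fry. All 35 lists had at least 3 tested members, and 7 of their 538 members were not tested. Beside the calls over all genes, members were also counted with the p-values adjusted over the list alone. The genes named are Ncoa2, a preset group of 14 genes, and the 8 with the largest log2 difference in each direction among called genes whose 3 mutant values all lay on one side of the 3 control values. To these come up to 4 called members per list with the smallest adjusted p, or up to 2 members with the smallest p where no member was called. Other members of the lists are named only to complete a count of 5 or fewer and were chosen after their values were seen. So were Akr1c18, Il36a, Il36b and Hoxa10, which are named beside the gene families. One gene that the rule takes in is not reported here.

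The other settings fixed in advance were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 2, and 3 other scalings (median of ratios, quantile, equal library totals). The others were eBayes without trend or robust, array weights, the replicate number as a block, and each library left out in turn. Chosen after the data were seen were edgeR (4.0.16, quasi-likelihood test) and DESeq2 (1.42.0) on the recovered whole reads, a mean of at least 100, and a correction for GC content and transcript length. The correction used GENCODE M21 and covered 33154 of the tested genes. DESeq2 gave no adjusted p for 6467 genes, which were left out of its calls.

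The procedure was tested on simulated data with the means and library sizes of the real samples. The changed genes were drawn from those with a mean normalized count of at least 100. For the comparison of mutants with controls, limma recovered 81% of 100 genes changed 4-fold and 13% of 100 genes changed 2-fold among 35702 genes. Of its 102 calls 8 were unchanged genes, and with no gene changed it made 0 calls, edgeR 0 and DESeq2 43. With the same data edgeR recovered 82% and 12%. DESeq2 recovered 97% and 34%, but 35.1% of its calls were unchanged genes. Far fewer genes were changed here than were called in the real data, which makes the adjusted p threshold stricter. These shares therefore do not carry over to the real contrast. Of 200 simulated unchanged lists, camera gave 8 a p under 0.05. The simulated genes were drawn independently of each other. That count therefore does not show how camera behaves where the genes of a list vary together.

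Genes of near-identical families, such as Sprr2, Prss28 with Prss29, Klk1b and the clustered histones, can share reads, and their single values are uncertain. The same holds for overlapping and antisense genes.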

Results

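The series measured the transcriptome of whole uterus on gestation day 5, around the time of embryo implantation, in 3 control (SRC-2f/f) and 3 mutant (SRC-2d/d) mice. Its stated purpose was to find the genes through which SRC-2 acts in implantation, and control against mutant was the one comparison. Between 129905950 and 195782326 reads were assigned to genes per library, and 31190 to 33435 genes had at least 1 read. The 10 most abundant genes held 7.39% to 10.2% of the reads of a library. Across the 17979 genes with a mean of at least 100, the first principal component held 70.7% of the variance and separated the genotypes. On it, the controls lay between -85.9 and -49.3, mutants 1 and 3 at 84.2 and 97.0, and mutant 2 at 28.9. Correlations across genes were 0.975 to 0.986 between controls, 0.954 to 0.963 between mutants and 0.871 to 0.947 between genotypes, the highest being those of mutant 2. Genes are not independent replicates, so these values only describe the libraries.

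Ncoa2, which encodes SRC-2, was lower in each mutant library than in each control library. Its normalized counts were 13208, 13090 and 14495 in controls 1 to 3 and 7620, 6667 and 7409 in mutants 1 to 3. The means were 13598 ± 779 in controls and 7232 ± 501 in mutants (SD, n = 3), which is 53.2% of the control level. The log2 difference was -0.91 (SE 0.20, adjusted p = 0.00953), and the exact permutation test gave p = 0.1, the smallest that 3 against 3 mice allow. The call was lost without control 2 (-0.94, adjusted p = 0.0583), without control 3 (-0.86, adjusted p = 0.0585) and with eBayes without trend (adjusted p = 0.119), the adjusted p of all alternatives being 0.00254 to 0.119. Reads from undeleted parts of the gene count towards it, and the deleted part is not given in the sources used here.

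Ltf, which encodes the secreted protein lactoferrin, rose from 721 ± 74.2 to 595620 ± 504270 normalized counts, 826-fold, and 434-fold without mutant 1. Clca1, a secreted regulator of chloride channels, had the largest log2 difference of all (11.32, SE 0.87, adjusted p = 2.37e-06), with 15265 in mutant 2 and 556928 in mutant 3. Its ratio of means was 5880, and 1380 without mutant 3. In the other direction, the gland-secreted protease gene Prss28 fell from 71172 ± 32638 to 384 ± 164 (log2 difference -7.49, SE 0.36, adjusted p = 5.32e-08). Bmp2, a growth factor needed for decidualization, fell from 19384 ± 11330 to 1149 ± 96.2 (-3.82, SE 0.41, adjusted p = 4.94e-05), so that 5.93% of the control level was left.

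In all, 1929 genes were higher and 1476 lower in mutants among 36154 tested, and 1721 and 1265 of these differed at least 2-fold. The 3 mutants lay above the 3 controls for 1904 of the higher genes and below them for 1394 of the lower genes. Of all tested genes 25.5% were separated in this way, against an average of 10% over all splits of the libraries into 3 and 3. Genes vary together, so a single split can lie far from that average, and 25.5% does not exclude chance. On the recovered reads edgeR called 1815 genes higher and 1057 lower, of which 1728 and 1018 were also called by limma. Counts depended on single libraries. The number of lower genes was 906, 452 and 315 without control 1, 2 or 3 and 819, 2813 and 761 without mutant 1, 2 or 3, and that of higher genes was 1093 without control 2 and 1013 without control 3. The 2986 genes changed at least 2-fold became 1540, 1319, 1944 and 4734 without control 2, control 3, mutant 3 and mutant 2. Among called genes named below, Spp1, Gpx3, Snai1, Aldoc, Oxtr, Pdpn and S100a8 lost the call with eBayes without trend alone, at an adjusted p of 0.0554 to 0.0703, and had values down to 6.72e-13 in the other alternatives. That fit also ended the calls of Tgfbi, Mmp2, Cdh11, Slc16a3, Pfkfb4, Ptges, Pla2g4a, Ptgfr, Pdgfra, Pi16, Des, Cdh5, Rrm2 and Wt1 (adjusted p of 0.118 to 0.161, and 6.01e-06 to 0.161 over all their alternatives), which removal of single libraries ended as well.

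Besides Ltf and Clca1, the largest rises were those of Lpo, Uox, Sprr2a3, Otop1, Unc5cl and Krt6b. Uox encodes urate oxidase and Lpo lactoperoxidase. Unc5cl went from 82.4 ± 42.0 to 37131 ± 16985 (log2 difference 8.83, SE 0.44). Otop1 had 3 reads in the controls together and a ratio of 1330 (95% counting interval 463 to 6570), and ratios of 3050 without control 2 and 888 without control 3. No read of Krt6b was found in the controls, which puts it at least 443-fold higher in mutants against a floor of 3 reads per library and at least 62.1-fold without mutant 1, but its call was lost with scaling to equal library totals (adjusted p = 0.216, and 1.08e-05 to 0.216 over all alternatives). The largest falls were those of Prss56, Fgg, Spink1, Acp7, Prl8a2, Prss28, Fga and Cyp11a1. Fgg and Fga encode chains of fibrinogen and Cyp11a1 the side-chain cleavage enzyme of steroid synthesis. Fgg fell from 851 ± 91.2 to 2.79 ± 2.54 (log2 difference -8.16, adjusted p = 4.23e-06), the control level being 305 times as high and 499 times without mutant 3, and Cyp11a1 stood 99.8 times as high in controls as in mutants (-7.17, adjusted p = 9.21e-05), and 205 times without mutant 2. Acp7 had 1 read in the mutants together, in mutant 2, and its control level was 937 times as high (interval 175 to 38500), and at least 110 times against that floor without mutant 2.

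**Figure D1:**
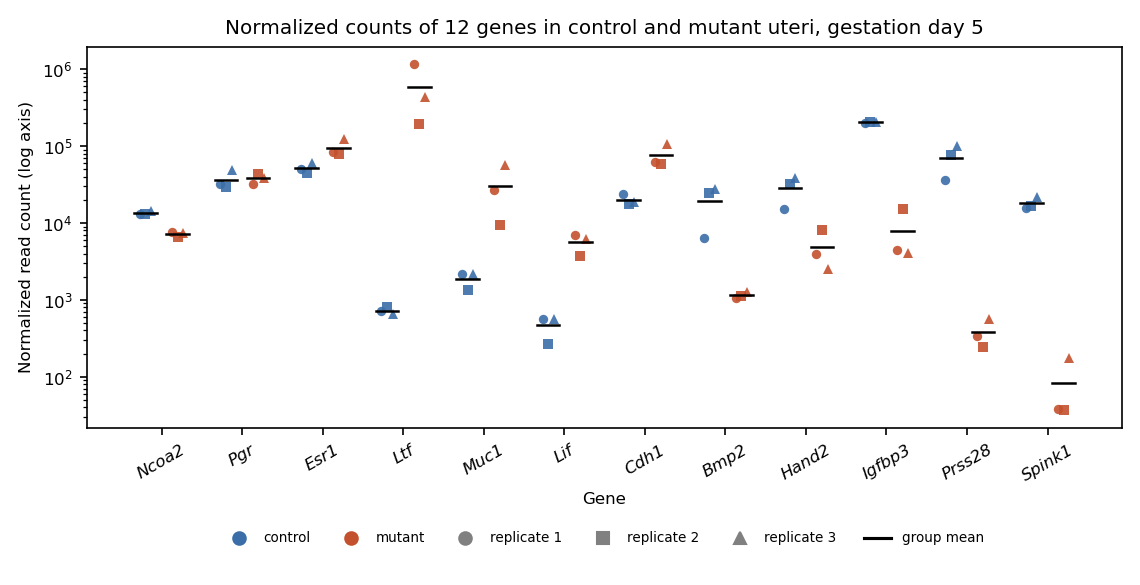
Normalized read counts (log axis) of 12 genes in the 3 control (blue) and 3 mutant (orange) libraries, with a marker shape per replicate number and a black bar at each group mean. Ncoa2 stands at 53.2% of the control mean, Pgr overlaps between genotypes, Esr1, Ltf, Muc1, Lif and Cdh1 lie above the controls in each mutant, and Bmp2, Hand2, Igfbp3, Prss28 and Spink1 lie below.

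Of the 35 gene lists fixed in advance, camera called 10 higher and 7 lower in mutants. With an estimated inter-gene correlation it called 0, with 5 lists at an unadjusted p under 0.05, and fry called 9. In the lists with 0 called members in a direction, edgeR called 0 in that direction too, and at most 5 members (mitochondrially encoded transcripts, higher) had an unadjusted p under 0.05 by limma. Without 1 library such counts were at most 2 (erythroid genes, higher without mutant 3). The list of the epithelial estrogen response led the higher ones. Of its 25 members 17 rose, 2 (Fgf9 and Igf1) fell and 6 were not called (17 rose and 3 fell adjusted over the list alone), with a median log2 difference of 3.70 (camera adjusted p = 2.96e-19, adjusted p = 0.0709 with an estimated correlation). The call of Fgf9 was lost on removal of any 1 library, with log2 differences of -1.34 to -0.76, and that of Igf1 without control 3 (-1.12), and edgeR called 1 of the 2. The median was the same with Sprr2a1, which had no read in the controls, at its bound. Sprr2f, a cornified-envelope gene with close paralogs, rose from 581 ± 222 to 216420 ± 80201. Padi1, a peptidylarginine deiminase, rose from 504 ± 137 to 149480 ± 79304, and Lcn2, the iron-siderophore carrier lipocalin 2, from 988 ± 461 to 130200 ± 77096.

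Luminal epithelial genes rose in 14 of 16 cases, with 1 (Wnt7b) lower and 1 not called (14 and 1 adjusted over the list alone), at a median of 2.02 (camera adjusted p = 5.47e-16, adjusted p = 0.0962 with an estimated correlation). Cbr2, a carbonyl reductase, rose 56.7-fold (34.9-fold without mutant 3), Calb1, which encodes the calcium-binding calbindin, 29.3-fold, and Ehf, an epithelial ETS factor, 6.89-fold. Of the 14 calls 10 held without each library in turn. Wnt7b went the other way, from 31134 ± 2919 to 4743 ± 749 (log2 difference -2.72, SE 0.21, adjusted p = 2.37e-06). Among 24 adherens-junction, desmosome and keratin genes 16 rose and 2 (Cdh3 and Nectin1) fell (18 and 2 adjusted over the list alone), at a median of 1.65 (camera adjusted p = 4.62e-15, adjusted p = 0.308 with an estimated correlation). Of the 16 calls 15 held without each library in turn, and those of Cdh3 and Nectin1 were lost without control 2 (-1.05 and -1.69) and without control 3 (-0.84 and -1.31). The desmosomal genes Dsp and Dsc2 rose 8.29-fold and 13.5-fold (Dsc2 8.26-fold without mutant 3), Krt19 rose 10.5-fold, and Cdh1, which encodes E-cadherin, rose from 20123 ± 3299 to 76304 ± 27134 (log2 difference 1.88, SE 0.26, adjusted p = 0.000363).

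Tight-junction genes were higher in 13 and lower in 2 (Esam and Jam3) of 29 cases (18 and 4 adjusted over the list alone; camera adjusted p = 6.46e-06, adjusted p = 0.0709 with an estimated correlation). Of the 13 calls 9 held without each library in turn, and those of Esam and Jam3 were lost without control 2 (-1.19 and -1.27) and without control 3 (-1.06 and -1.19), that of Esam also without mutants 1 and 3 (-1.14 and -0.91). Cldn7 rose 5.76-fold and the scaffold gene Tjp3 10.6-fold. In the ion and water transport list 8 of 20 genes rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 5.96e-08, adjusted p = 0.0709 with an estimated correlation). Cftr, a chloride channel, rose from 262 ± 48.8 to 8473 ± 4894, and Fxyd4, a regulator of the sodium pump, 31.4-fold. The mucin and glycocalyx list had 5 of 14 members higher and 1, Mcam, lower (5 and 2 adjusted over the list alone; camera adjusted p = 0.0345, adjusted p = 0.366 with an estimated correlation). Muc1, a mucin of the luminal surface, rose from 1895 ± 461 to 30730 ± 23790, which is 16.2-fold and 9.47-fold without mutant 3, Muc4 rose 45.2-fold, and Muc20, Fut2 and Galnt3 rose as well. The call of Muc1 was lost with eBayes without trend (adjusted p = 0.0520, and 2.16e-16 to 0.0520 over all alternatives). Mcam was not called without controls 2 and 3 (-1.01 and -0.78) or mutants 1 and 3 (-0.81 and -0.92), and without mutant 2 the list had 2 lower genes. That list's call was lost without control 1 (median 0.27, adjusted p = 0.133, and 5.68e-06 to 0.366 over all alternatives) and under 7 other settings, and its median of 0.14 was 0.23, 0.30, 0.33 and 0.03 without control 3, mutant 1, mutant 2 and mutant 3.

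Glandular genes split. Of 16 members 6 rose, 5 (Prss28, Prss29, Spink1, Ttr and Wfdc3) fell and 5 were not called (6 and 6 adjusted over the list alone), so that the median was 0.26 and the mean -0.84 and the list was not called (camera adjusted p = 0.755, direction down). The median was -0.01 without control 2, 0.12 without mutant 1 and 0.02 without mutant 3. Spink1, a secreted protease inhibitor, fell from 18121 ± 3510 to 83.4 ± 79.6 (to 0.461% of the control level, and 0.207% without mutant 3), and Prss29 fell from 127460 ± 59490 to 860 ± 217. Fxyd4 rose, as did Lif, the cytokine required for implantation, which went from 464 ± 173 to 5640 ± 1704 (log2 difference 3.63, SE 0.33, adjusted p = 1.06e-05). Foxa2, a gland transcription factor, stood at 607 ± 237 and 305 ± 113 (adjusted p = 0.132). The 20 genes of implantation and the LIF pathway had 5 higher (Lif, Lifr, Msx1, Msx2 and Spp1) and 3 lower (Areg, Ereg and Gpx3; 6 and 4 adjusted over the list alone), and the list, with a median of 0.30 and a mean of -0.01, was not called (camera adjusted p = 0.361, direction up). Its median was 0.18 without control 1. The 5 higher genes were 3, 2 and 3 without control 1, control 3 and mutant 3, and the 3 lower ones were 5 without mutant 2. The call of Lifr was lost without controls 2 and 3 and mutant 3 (0.95, 1.01 and 0.78), that of Msx1 without controls 1 and 3 and mutants 2 and 3 (0.74, 0.92, 0.77 and 0.89), and that of Msx2 without controls 1 and 3 (2.15 and 2.17). The EGF-family gene Ereg fell from 193 ± 12.9 to 5.64 ± 6.02 (-5.28, adjusted p = 0.000295), or 2.92% of the control level and 1.15% without mutant 2, while Hbegf stood at 1286 ± 92.9 and 1485 ± 130 (adjusted p = 0.665) and Ptgs2 at 1416 ± 571 and 2062 ± 957 (adjusted p = 0.514). Areg, another gene of that family, had a log2 difference of -4.04 (adjusted p = 0.00513). It was not called without control 1 (-3.82, adjusted p = 0.0584), without control 3 (-4.04, adjusted p = 0.0673), with eBayes without trend or robust, by edgeR (0.0509) or by DESeq2 (0.0519), and its adjusted p ran from 5.39e-06 to 0.123 over all alternatives.

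Among 13 steroid receptor and coactivator genes 2 (Esr1 and Esr2) rose and 1, Ncoa2, fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.141). That list was called without control 3 (median 0.30, adjusted p = 0.0176, and 0.0176 to 0.758 over all alternatives). The progesterone receptor gene Pgr stood at 36624 ± 10338 in controls and 38125 ± 5390 in mutants (log2 difference 0.08, SE 0.24, adjusted p = 0.879). The estrogen receptor gene Esr1 stood at 51764 ± 7659 and 95588 ± 24272 (0.87, SE 0.24, adjusted p = 0.0379), a call that was lost on removal of any library other than mutant 2 (adjusted p of 0.0967, 0.186 and 0.0728 without controls 1 to 3 and of 0.0795 and 0.148 without mutants 1 and 3) and under 3 other settings. Esr2, the second estrogen receptor gene, had 13.4 ± 9.08 and 91.5 ± 64.0 (2.74, SE 0.75, adjusted p = 0.0349), and was not called without controls 1 to 3 (2.05, 3.20 and 2.97), without mutant 3 (2.21) or under 5 other settings, with adjusted p = 0.00125 to 0.160 over all alternatives. The list of the progesterone response and Indian hedgehog pathway had 3 of 25 members (Hdc, Lrp2 and Sox17) higher and 7 lower (3 and 15 adjusted over the list alone; camera adjusted p = 0.0012, adjusted p = 0.647 with an estimated correlation). Its median was -0.89, and -0.58 without mutant 3. The list mean of mutant 2 was 13.22, inside the control range of 13.13 to 13.29, while mutants 1 and 3 lay at 12.05 and 11.83. The 7 lower genes were 4, 3, 16 and 4 without control 2, control 3, mutant 2 and mutant 3. The call of Sox17 was lost without controls 1 to 3 (0.96, 1.11 and 1.09), as was that of Lrp2 (1.44, 1.32 and 1.21). Calca, which encodes calcitonin, fell from 319 ± 70.3 to 18.3 ± 21.1, or 5.75% of the control level and 1.93% without mutant 2, whereas Hdc, the histamine-forming enzyme, rose 4.73-fold. Ihh, the epithelial hedgehog ligand, had 6547 normalized counts in mutant 2 but 872 and 917 in mutants 1 and 3, against 3326 to 5978 in controls. It was not called (-1.26, adjusted p = 0.210), but was without mutant 2 (-2.22, adjusted p = 5.94e-05, and up to 0.768 over all alternatives).

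Decidualization genes were lower in 18 of 26 cases, higher in 2 (Alpl and Bmp8a) and not called in 6 (19 lower and 2 higher adjusted over the list alone), at a median of -1.36 (camera adjusted p = 1.77e-12, adjusted p = 0.350 with an estimated correlation). The 18 lower genes were 10 without control 2 and 10 without control 3, and edgeR called 17. Bmp8a was not called without controls 1 to 3 (1.29, 2.04 and 2.01) or mutants 1 and 3 (1.38 and 1.80). Igfbp3, a binding protein of insulin-like growth factors, fell from 203780 ± 5702 to 7876 ± 6216. Tdo2, which degrades tryptophan, fell from 13684 ± 5259 to 365 ± 375, and the decidual prolactin-family gene Prl8a2 fell from 480 ± 291 to 1.79 ± 2.42. Without mutant 2, 2.10% rather than 3.86% of the control level of Igfbp3 was left and 1.10% rather than 2.67% of that of Tdo2, and without mutant 1 0.0862% rather than 0.373% of that of Prl8a2. Hand2, a progesterone-dependent transcription factor of the stroma, was left at 16.7% of the control level (-2.64, SE 0.39, adjusted p = 0.000661), and at 11.1% without mutant 2, with a call lost with eBayes without trend (adjusted p = 0.0772, and 2.54e-08 to 0.0772 over all alternatives). Wnt4 stood at 6931 ± 3402 and 3481 ± 1774 (-1.03, adjusted p = 0.167), and was called with array weights (-1.19, adjusted p = 0.0403, and 0.0403 to 0.555 over all alternatives). Control 1 had the lowest list mean of the controls, 12.37 on the log2 scale against 13.20 and 13.40, and the mutants lay at 11.25, 11.38 and 10.97.

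In the Wnt pathway list 8 of 24 genes fell and 2 (Rnf43 and Wnt7a) rose (15 and 4 adjusted over the list alone; camera adjusted p = 2.12e-05, adjusted p = 0.308 with an estimated correlation). The 8 lower genes were 13 without mutant 2, and Wnt7a was not called without control 2 (1.06) or control 3 (0.98). The secreted inhibitor genes Sfrp1 and Sfrp4 fell from 6557 ± 1188 to 1081 ± 137 and from 26744 ± 5040 to 6342 ± 1349. Among 14 markers of endometrial stroma 5 fell (Hand2, Hoxa11, Pdgfra, Pi16 and Vcan) and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 2.12e-05, adjusted p = 0.479 with an estimated correlation). Pdgfra, a receptor of platelet-derived growth factor, had a log2 difference of -1.42 (adjusted p = 0.00849), a call lost without control 3 (-1.23, adjusted p = 0.0838, and 0.000264 to 0.144 over all alternatives). The call of Pi16 was lost without controls 2 and 3 (-1.17 and -1.08), that of Hoxa11 without controls 2 and 3 and mutants 1 and 3 (-1.32, -1.23, -1.22 and -1.11), and that of Vcan without controls 1 and 3 and mutant 3 (-1.92, -1.71 and -1.52) and under 4 other settings. The 5 lower genes were 3, 1, 8 and 3 without control 2, control 3, mutant 2 and mutant 3. Mesenchymal transition factors and markers had 5 of 21 members (Snai1, Tgfbi, Mmp2, Cdh11 and Vim) lower and 0 higher (12 and 0 adjusted over the list alone; camera adjusted p = 2.19e-07, adjusted p = 0.479 with an estimated correlation), with Snai1 falling from 9942 ± 4766 to 1063 ± 915, the control level being 9.35 times as high and 18.5 times without mutant 2. Tgfbi and Mmp2 were not called without control 3 (-1.37 and -1.46), Cdh11 not without controls 2 and 3 and mutant 1 (-1.19, -0.99 and -0.96), and Vim not on removal of any library other than mutant 2 (-1.22, -1.13 and -0.97 without controls 1 to 3 and -1.01 and -0.81 without mutants 1 and 3). Without mutant 2 there were 13 lower genes. Mutant 2 lay close to the controls on these lists. Its stroma list mean was 15.60, against 15.67 to 16.13 in controls and 14.69 and 14.55 in mutants 1 and 3, and its mesenchymal mean was 12.88, against 13.13 to 13.45, 12.22 and 11.98.

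**Figure D2:**
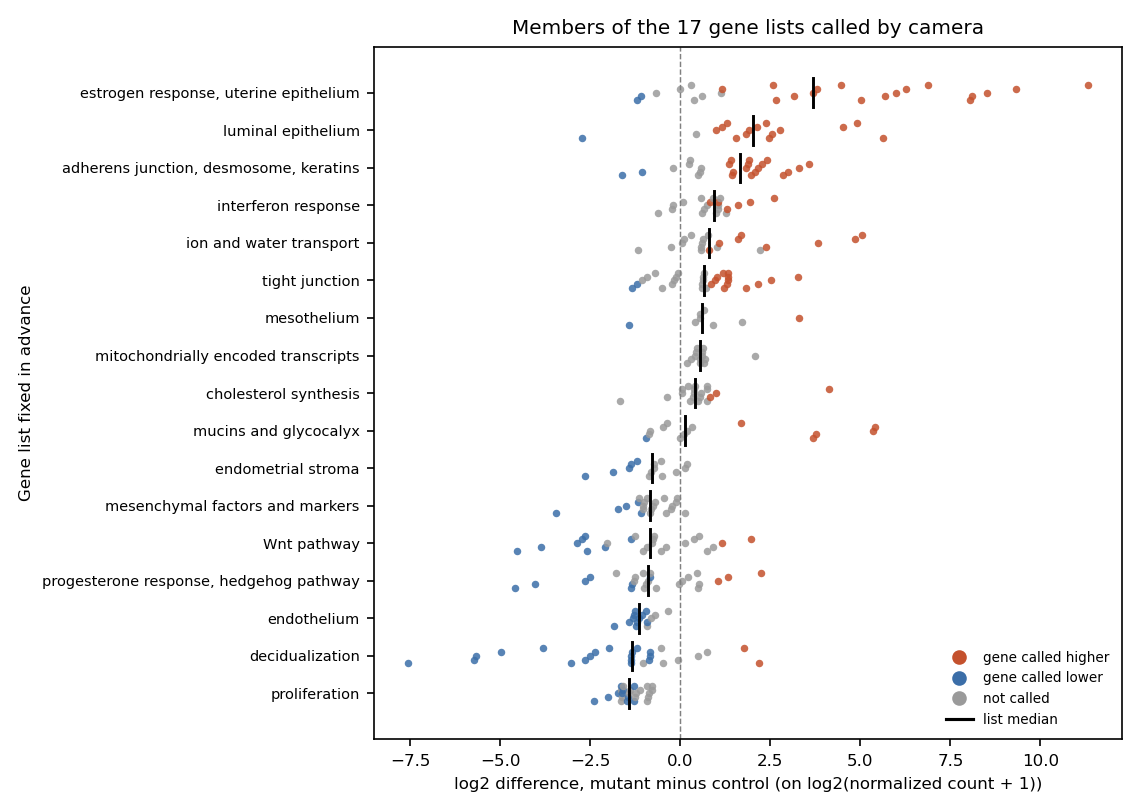
Each point is a gene's log2 difference (mutant minus control, on log2(normalized count + 1)) in 1 of the 17 lists called by camera, with genes called higher in orange, genes called lower in blue, genes not called in grey and a black bar at the list median. The medians run from -1.43 for proliferation to 3.70 for the epithelial estrogen response.

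Endothelial markers were lower in 11 of 15 cases and higher in 0 (14 and 0 adjusted over the list alone; camera adjusted p = 9.99e-10, adjusted p = 0.479 with an estimated correlation). edgeR called 6 of them lower. By limma there were 3, 2 and 0 without controls 1 to 3 and 4, 14 and 4 without mutants 1 to 3. Cdh5, the cadherin of endothelial junctions, fell from 46992 ± 18137 to 14014 ± 8570 (-1.84, adjusted p = 0.00495), or to 29.8% of the control level and 19.3% without mutant 2, but was not called without control 3 (-1.54, adjusted p = 0.0710, and 4.52e-05 to 0.135 over all alternatives) or with eBayes without trend or robust (0.135 and 0.0529). Of 7 lymphatic markers 1, Pdpn, fell and 0 rose (2 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0835). The lymphatic list was called lower without control 3 (median -0.59, adjusted p = 0.0315) and without mutant 3 (-0.49, adjusted p = 0.0279) and with the correction for GC content and length (-0.48, adjusted p = 0.0397), with 0.0279 to 0.567 over all alternatives. Without mutant 2 there were 2 lower and 1 higher lymphatic markers, and without control 1 1 lower and 1 higher. Smooth muscle had 1 of 13 markers higher and 1 lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.361), the higher one being the oxytocin receptor gene Oxtr, at 3.04-fold, and the lower one the desmin gene Des. The call of Des was lost without control 3 (-1.11) and mutants 1 and 3 (-1.22 and -1.01), and without mutant 2 there were 3 lower markers. Proliferation genes were lower in 10 of 25 cases and higher in 0 (24 and 0 adjusted over the list alone; camera adjusted p = 4.79e-12, adjusted p = 0.479 with an estimated correlation). Only 1 of the 25 was called lower by edgeR, and by limma there were 2, 1 and 0 without controls 1 to 3 and 1, 25 and 1 without mutants 1 to 3. Rrm2, a subunit of ribonucleotide reductase, fell from 34978 ± 17398 to 6920 ± 4413 (-2.39, adjusted p = 0.00379), or to 19.8% of the control level and 12.9% without mutant 2, and was not called without control 3 (-2.06, adjusted p = 0.0698, and 6.01e-06 to 0.131 over all alternatives) or with eBayes without trend or robust (0.131 and 0.127). The proliferation mean of mutant 2 was 13.35, inside the control range of 13.10 to 13.99, while mutants 1 and 3 lay at 11.13 and 12.14. Without mutant 1 the list median went from -1.43 to -0.81. On the endothelial list mutant 2 lay at 13.09, against 13.35 to 13.84 in controls and 12.21 and 11.97 in the other mutants.

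**Figure D3:**
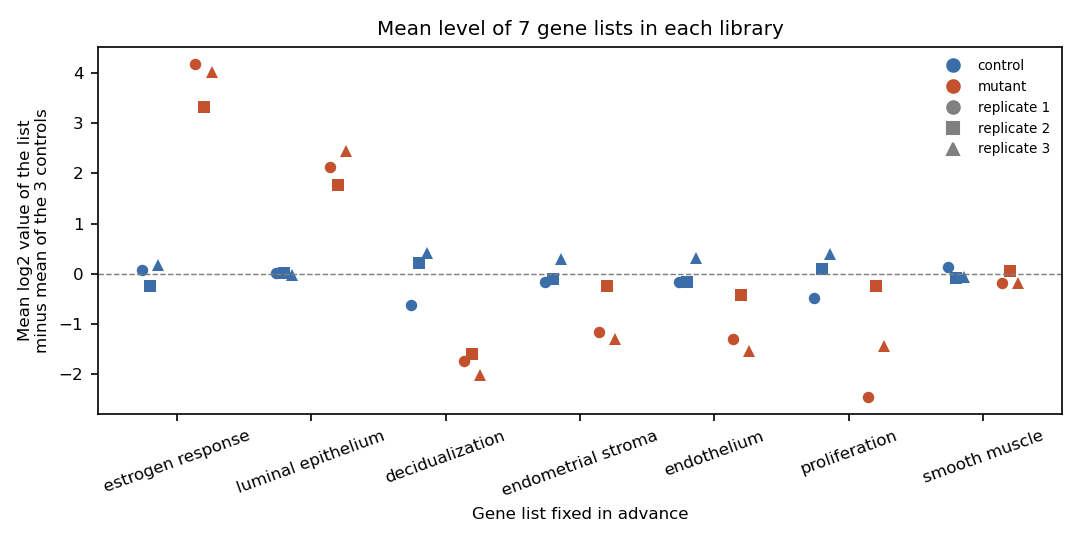
Mean log2(normalized count + 1) of 7 gene lists in each library, after subtraction of the mean of the 3 controls, with controls in blue, mutants in orange and a marker shape per replicate number. Mutant 2 (square) lies with the other mutants on the decidualization list (11.38, against 11.25 and 10.97) and near the controls on the stroma list (15.60, against 15.67 to 16.13).

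The interferon response list had 6 of 20 members higher and 0 lower (13 and 0 adjusted over the list alone; camera adjusted p = 2.77e-05, adjusted p = 0.567 with an estimated correlation). edgeR called 4 of them higher, and limma 0 without control 2, control 3, mutant 1 or mutant 3 and 11 without mutant 2. Irf7, a transcription factor of that response, stood at 7494 ± 2241 and 25746 ± 15854, a call lost on removal of any library other than mutant 2 and under 4 other settings (adjusted p = 7.61e-05 to 0.225 over all alternatives). Without control 1 its log2 difference was 1.82, without control 2 1.53, without control 3 1.42, and without mutants 1 and 3 1.48 and 1.13. Control 1 had an interferon list mean of 12.85, above the 12.77 of mutant 1 and the 12.22 of mutant 2, while controls 2 and 3 lay at 11.50 and 11.61. In cholesterol synthesis 3 of 19 genes rose and 0 fell (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000707, adjusted p = 0.479 with an estimated correlation). Msmo1, which encodes a sterol monooxygenase, had a log2 difference of 0.99 (SE 0.24, adjusted p = 0.0189). That call was lost without controls 1 to 3 (0.98, 0.95 and 1.04), without mutants 1 and 3 (1.00 and 0.79) and with eBayes without trend, with adjusted p = 0.00377 to 0.158 over all alternatives. The 3 calls became 1 on removal of any library other than mutant 2, and 5 without mutant 2, where 1 gene was lower. Of 17 prostaglandin genes 5 rose (Lpar3, Pla2g4a, Ptgds, Hpgd and Hpgds) and 2 fell (Ptges and Ptgfr; 6 and 2 adjusted over the list alone; camera adjusted p = 0.172). The 5 higher genes were 3, 2 and 1 without controls 1 to 3, 2 and 3 without mutants 1 and 3 and 3 by edgeR. Ptges was not called without controls 2 and 3 (-1.45 and -1.26), Ptgfr without controls 1 to 3 and mutant 1 (-1.15, -1.19, -1.15 and -0.87), and Pla2g4a without controls 1 and 3 (1.23 and 1.46). Lpar3, a lysophosphatidic acid receptor gene, rose 3.44-fold. Glycolysis had 1 of 21 genes higher and 2 (Slc16a3 and Pfkfb4) lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.172), with Aldoc 11.6-fold higher, and 6.18-fold without mutant 3. Slc16a3 was not called without control 3 (-1.29), nor Pfkfb4 without controls 2 and 3 and mutant 1 (-0.96, -0.83 and -0.98), and there were 4 lower genes without control 1 and 4 without mutant 2. Of 15 immediate-early genes Ier3 rose 6.02-fold and 1, Myc, fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.387). Myc, with a log2 difference of -1.17 (adjusted p = 0.0212), was not called without controls 1 to 3 (-1.21, -1.19 and -1.11), without mutants 1 and 3 (-1.17 and -0.83), by edgeR (adjusted p = 0.0537) or under 2 other settings, with 0.000627 to 0.205 over all alternatives. Without mutant 2 there were 5 lower immediate-early genes. The glycolysis list was called without control 1 (median -0.26, adjusted p = 0.00733, and 0.00733 to 0.846 over all alternatives).

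Markers of other cell types were mostly not called. Macrophage and natural killer lists had 0 called members of 11 each (0 adjusted over the list alone), at camera adjusted p = 0.298 and 0.882. Adgre1 stood at 5463 ± 1368 and 8020 ± 2359 (adjusted p = 0.233), and Gzmb at 13164 ± 3851 and 7798 ± 4279 (adjusted p = 0.143), the latter called without mutant 2 (-1.26, adjusted p = 0.00476, and 0.00476 to 0.440 over all alternatives) and with array weights (0.0406). The macrophage list was called higher without control 1 (median 0.28, adjusted p = 0.0124, and 0.0124 to 0.787 over all alternatives). The natural killer list had a median of -0.04, which ran from -0.34 without mutant 1 to 0.34 without mutant 3, and without mutant 3 it was called higher (0.34, adjusted p = 0.0418, and 0.0418 to 0.972 over all alternatives). Among 13 T and B cell genes 1, Cd79b, was higher (1 adjusted over the list alone; camera adjusted p = 0.658), a call lost without controls 2 and 3 (1.70 and 1.78) and under 2 other settings. Of 10 neutrophil genes 1 rose and 2 (S100a8 and Camp) fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.754). Ly6g was 38.0-fold higher, and 13.9-fold without mutant 3, a call lost with scaling to equal library totals (adjusted p = 0.0762, and 1.54e-06 to 0.0762 over all alternatives), and S100a8 was left at 25.6% of the control level. Camp, at 80.8 ± 4.67 and 15.3 ± 19.7 (-3.52, adjusted p = 0.0459), was not called in 12 of 20 alternatives. These were the fits without controls 1 to 3 (-3.50, -3.50 and -3.57) and without mutant 3 (-2.11), edgeR (adjusted p = 0.163) and 7 other settings, with 0.0056 to 0.222 over all alternatives. Erythroid genes had 0 of 7 called (0 adjusted over the list alone; camera adjusted p = 0.213), and that list was called higher without mutant 3 (median 0.95, adjusted p = 0.000495, and 0.000495 to 0.887 over all alternatives).

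Adipocyte genes differed widely within both genotypes, with 0 of 8 called (0 adjusted over the list alone; camera adjusted p = 0.0725). Their list means were 9.78, 6.87 and 4.46 in controls 1 to 3 and 9.45, 7.04 and 9.30 in mutants 1 to 3, and the list was called higher without control 1 (median 3.34, adjusted p = 0.000171) and without mutant 2 (2.79, adjusted p = 0.00826), with the replicate number as a block (1.83, adjusted p = 0.0358) and with array weights (1.52, adjusted p = 0.0434), with 0.000171 to 0.865 over all alternatives. The median over all libraries was 1.83, and without control 3 it was 0.10 (camera adjusted p = 0.755). The mesothelium list had 1 of 8 members higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.0173, adjusted p = 0.479 with an estimated correlation). The higher one was Krt19, also an epithelial keratin, and the lower one Wt1, also a stromal gene, at 30343 ± 7441 and 11368 ± 3561, whose call was lost without control 3 (-1.29). The call of the list was lost without control 3 (median 0.32, adjusted p = 0.0900) and without mutant 1 (0.44, adjusted p = 0.0731), with scaling to equal library totals (0.0546), with eBayes without trend (0.0676), with array weights (0.105), with a mean of at least 100 (0.0556) and with edgeR (0.0555), with 0.00124 to 0.479 over all alternatives, and the median of 0.60 was 0.93 without control 2. The higher genes were 2 without control 2 and 3 without mutant 2. Of 9 ciliated and oviduct genes 1 rose, the oviduct glycoprotein gene Ovgp1 at 5.94-fold, and 1, Dynlrb2, fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.882). Dynlrb2, with 1 read in the mutants together, was not called without control 2 (-3.54) or control 3 (-3.75). Of 10 ovary genes 1, Cyp11a1, fell (1 adjusted over the list alone; camera adjusted p = 0.141).

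Among 14 embryo and trophoblast genes 2 (Elf5 and Utf1) rose and 1, Tfap2c, fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.667). Utf1, at 23.8 ± 11.4 and 170 ± 110 (2.61, SE 0.66, adjusted p = 0.0235), was not called on removal of any library other than mutant 2 (2.63, 2.24 and 2.94 without controls 1 to 3 and 2.13 and 2.39 without mutants 1 and 3) or under 2 other settings, with adjusted p = 4.61e-05 to 0.130 over all alternatives. Elf5, also an epithelial transcription factor, rose from 45.2 ± 14.4 to 531 ± 185, and Tfap2c was left at 12.8% of the control level. Mitochondrially encoded transcripts had 0 of 13 members called (0 adjusted over the list alone) and a median of 0.55, and camera called the list (adjusted p = 0.00325, adjusted p = 0.647 with an estimated correlation). The median was 0.37 without control 3, and the call was lost with the correction for GC content and length (0.22, adjusted p = 0.142). The mitochondrial ribosomal RNA mt-Rnr2 stood at 139280 to 300148 in controls, at 337161 and 379879 in mutants 1 and 2 and at 1406336 in mutant 3. Of 4 tested X-inactivation and Y-linked genes 0 were called (0 adjusted over the list alone; camera adjusted p = 0.754), with Xist at 171800 ± 69162 and 209350 ± 35004 (adjusted p = 0.557).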

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

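edgeR, DESeq2, the mean of at least 100 and the correction for GC content and length were chosen after the results were seen. The counts moved most with the variance model, the scaling to equal library totals and single libraries. With eBayes without trend 683 genes were higher, 315 lower and 998 changed at least 2-fold, and Ncoa2 was no longer called (log2 difference -0.91, adjusted p = 0.119, against 0.00254 to 0.0585 in its other alternatives). Scaling to equal library totals gave 1024 higher, 821 lower and 1215 changed at least 2-fold. Its values are smaller, so that a pseudocount of 1 weighs more on them. With array weights 2500 genes were lower. The cause of the other shifts was not tested. With an estimated correlation camera called 0 lists. Over the fits without 1 library, which have fewer samples, 1013 to 2598 genes were higher, 315 to 2813 lower and 1319 to 4734 changed at least 2-fold, and 16 to 20 lists were called. The log2 difference of Ncoa2 went from -0.95 to -0.85. The lowest gene counts came without control 3 and the highest without mutant 2. The natural killer list changed direction and was called without mutant 3 (median 0.34, adjusted p = 0.0418, and -0.34 at the lowest without mutant 1). No called gene was called in the opposite direction under any alternative run (0 genes). For named genes 2299 comparisons with an alternative kept the side of the threshold, 205 lost the call and 6 gained it. For lists 722 kept that side, 33 lost the call and 11 gained it. A change of direction where neither fit made a call was counted among those kept. The labels do not say whether replicate numbers pair the mice, and correlations over 3 mice per genotype cannot decide it. Same-numbered libraries had correlations of 0.38, 0.015 and 0.027 of their deviations from the group means. Differently numbered libraries had -0.41 to 0.34, and control 2 correlated best with mutant 1 (0.024). With the replicate number as a block 2104 genes were higher and 1708 lower. No scaling moved the median of all genes by over 0.1. Median-of-ratios and quantile scaling largely fix that median by construction, so it does not show that the calls withstand the choice of scaling. Depth limits genes near 3 reads per library. Among simulated 2-fold changes of genes with a mean of at least 100, limma recovered 13%. Far fewer genes were changed there than were called in the real data, so that share does not carry over to the real contrast. Recovery of genes with lower counts was not measured.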

Other observations

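The tests of gene families, of a larger epithelial or smaller stromal share, and both tests on mutant 2 were chosen after the results were seen. The grouping of the families and the choice of genes for the test of mixed RNA were each revised once after a first result, without a change in what the latter test showed. Gene families, taken from the root of the symbol, showed further groups. Of 306 families with at least 8 members and a mean of at least 10, 10 held more higher genes and 7 more lower genes than the other genes did (Fisher's exact test, one-sided, adjusted p under 0.05 over 612 tests). These tests treat genes as independent, whereas members of a family can vary together and were measured in the same mice. Their p-values therefore do not measure variation between mice. Clustered histone genes, whose transcripts are made during DNA replication, were lower in 32 of 61 cases against 5.12% of other genes (adjusted p = 2.12e-22), with a median log2 difference of -1.49 and of -1.34 to -1.51 under the other scalings. edgeR called 9 of them. Their mean log2 value was 12.53 in mutant 2, inside the control range of 12.29 to 13.48, and 10.72 and 11.20 in mutants 1 and 3, and limma called 32, 5 and 5 lower without controls 1 to 3 and 7, 56 and 7 without mutants 1 to 3. Their reads can be shared between near-identical copies. The libraries were poly(A)-selected according to the labels' protocols. How completely that selection worked, and how far it set the level of histone transcripts in each library, was not tested. All 9 Sprr genes were higher (adjusted p = 1.1e-08), as were 12 of 28 keratins (adjusted p = 2.55e-05) and 5 of 8 Oas genes of the interferon response (adjusted p = 0.00454). The 5 Oas calls became 0 without control 2, control 3, mutant 1 or mutant 3, while edgeR called 5. Secreted or membrane-bound serine proteases were higher in 6 of 11 Klk and 6 of 11 Tmprss genes (adjusted p = 0.00285 each).

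Further families moved as well. Akr genes, among them the progesterone-degrading enzyme gene Akr1c18, were higher in 6 of 13 cases (adjusted p = 0.00682), and 16 of 67 interleukins and their receptors were higher (adjusted p = 0.00152), including Il36a and Il36b, but 10, 10 and 8 without controls 1 to 3. Hoxb genes were higher in 4 of 8 cases (Hoxb4, Hoxb6, Hoxb7 and Hoxb8, adjusted p = 0.046), while Hoxa10 and Hoxa11 were lower, with log2 differences of -1.35 and -1.37. The calls of both were lost without control 2 (-1.29 and -1.32), control 3 (-1.26 and -1.23) and mutant 3 (-1.09 and -1.11), and that of Hoxa11 without mutant 1 (-1.22). Adamts metalloproteases were lower in 7 of 19 cases (adjusted p = 0.00285), collagens in 10 of 42 (adjusted p = 0.00319) and Mcm replication helicase genes in 4 of 10 (adjusted p = 0.046). The 7 Adamts calls became 2, 1 and 1 without controls 1 to 3 and 4 and 2 without mutants 1 and 3, and the 10 collagen calls became 4, 3 and 2 without controls 1 to 3 and 4, 18 and 4 without mutants 1 to 3. edgeR called 4 Adamts genes, 5 collagens and 0 of the Mcm genes lower (5 of the last at an unadjusted p under 0.05), and limma called 8 Mcm genes without mutant 2 and 0 without any other library.

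Whether chance gave the contrast cannot be decided from 10 splits of 6 libraries into 3 and 3. The real split called 3405 genes and the highest of the others 0, so 1 of the 10 splits reached the real count. For lists the real split called 17 and the highest of the others 16, so again 1 split reached it. The 9 others called 16, 16, 16, 13, 11, 11, 8, 7 and 6 lists.

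Epithelial and estrogen-response genes were higher in mutants. A larger epithelial share alone would multiply transcripts made only by the epithelium by a common factor. The gap between the mean log2 values of the estrogen-response list and of the junction and keratin list was 2.43 higher in mutants (-0.385 ± 0.348 against -2.81 ± 0.175, SD, n = 3). Junction genes that other cells also make would rise less under a larger share, so this gap alone cannot decide. Glandular genes that fell, such as Spink1 (log2 difference -8.13) and Prss28 (-7.49), argue against a larger share as the whole cause. A bias from GC content or transcript length is argued against too, since the median of the estrogen-response list after correction was 103% of the uncorrected one (3.81 against 3.70). An altered state of the epithelium was not tested, and a shift between luminal and glandular cells, a larger epithelial share in addition and a difference in hormone levels between the mice were not tested either and may each contribute.

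Decidualization genes were lower in mutants. If the stroma list were made by stroma only, a smaller stromal share alone would lower decidualization genes by no more than that list. The gap between the lists, with shared members left out, differed by -1.06 (-4.24 ± 0.439 in mutants against -3.18 ± 0.460 in controls, SD, n = 3). By library the gap was -3.69, -2.81 and -3.03 in controls 1 to 3 and -3.90, -4.73 and -4.07 in mutants 1 to 3. Control 1 and mutant 1 lay close together. Stroma genes are also made by other layers of the uterus, which can shrink their fall under a smaller share. This gap therefore cannot decide whether a smaller share was the whole cause, and its contribution stays open. The scaling between samples is argued against because the median log2 difference of the decidualization list was at most -1.27 under the other scalings. What else lowered these genes was not tested, and neither was whether the sampled uteri held comparable numbers of implantation sites.

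Mutant 2 lay between the controls and the other mutants. Over the genes called without it, it had moved 60% of the way from the controls to mutants 1 and 3 for higher genes (median of 2598) and 37.3% for lower genes (median of 2813), while mutants 1 and 3 had positions of 101% to 120% when each was left out. The positions of mutants 1 and 3 are relative to a mean that includes mutant 2, over 761 to 1394 genes, so the scales differ. Control RNA mixed into the library is argued against by the 14 genes that stood under 2% of a control mean of at least 1000 in mutants 1 and 3, which had a median of 1.01% in mutant 2 (quartiles 0.38% and 4.86%, with Npy and Map7d2 at 10.1% and 11.8%). The Ncoa2 level of mutant 2 was not higher, at 88.7% of the mean of mutants 1 and 3. That level is of whole uterus and includes reads from undeleted parts of the gene. It therefore cannot show how complete the loss was in each cell type. Variation between mice, such as in the stage of pregnancy or in the cell types that lost the gene, may account for the position of mutant 2 and was not tested.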
